A study of Homo sapiens with 6 samples.

How the data were processed

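RNA sequencing libraries of OVCAR5 cells were compared between 3 libraries of cells treated with 100 nM NTX301 and 3 of cells treated with DMSO, each for 3 days. Per the labels' protocols, total RNA was extracted with TRI Reagent, DNA was removed with DNase on a clean-up column, and libraries were made with a NEBNext Ultra II RNA kit. Groups and replicate numbers were taken from the labels. The labels' protocols also name a 10 nM dose and methylation arrays, and these were not analysed here. Whether the replicates came from separate cultures is not stated in the labels.

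The authors deposited 1 gene table per library, whose columns, per the file headers, are those that RSEM writes. The deposited expected counts are estimated reads per gene, summed over the transcripts of the gene and not normalized, and need not be whole numbers. The deposited TPM values are relative transcript abundances, scaled by the authors' run of RSEM over all genes of a table. The deposited FPKM column was not used. Deposited files are named as alignments to the transcriptome in the form that STAR gives. The versions of these tools, the genome build and the annotation release are not given in the sources used here. Effective lengths were 74 bases below gene length in all genes over 500 bases, which implies reads of 75 bases and no model of fragment length. RSEM divides reads that match several genes by its own estimate, so near-identical copies such as HBA1 and HBA2, SAA1 and SAA2 or the TBC1D3 family, and readthrough transcripts such as BIVM-ERCC5, are uncertain. The strand setting of the counting is not given in the sources used here, so reads of genes that overlap on opposite strands may not have been separated. Of the 82 named genes, 21 overlap another tested gene on the other strand.

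Each table had 62703 entries. The 47 entries of pseudoautosomal genes on chromosome Y, with 0.0224% of all counts, were added to their X copies, which left 62656 genes, of which 62639 matched a table of gene names by stable identifier. Positions and gene types were taken from GENCODE 29 (GRCh38) by stable identifier for 58220 genes. The annotation of the files is newer than that release, but all 34740 genes with 1 transcript of the same identifier and version in both had the same transcript length. Symbols were not used to join tables.

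Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): genes were kept by filterByExpr (19029 genes), libraries were scaled by TMM (factors 0.9206 to 0.939 for DMSO and 1.0679 to 1.0834 for NTX301), and glmQLFit and glmQLFTest were fitted to all 6 libraries with treatment as the only term. P-values were adjusted by Benjamini-Hochberg over the tested genes with a threshold of 0.05. The common biological coefficient of variation was 0.0478. CPM values are rounded counts scaled by the library total times its TMM factor, and levels are given as mean ± SD over 3 libraries. Errors of log2 fold changes are standard errors derived from the fold change and the F statistic. A gene was called on in 1 group and off in the other where its counts summed to 3 or fewer over the 3 libraries of 1 group and reached 1 CPM in each library of the other. Where a gene had 0 counts in a group, the fold was computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with an exact 95% interval for the counting error. Library pairs within a group differed by 2.37 to 6.57 in chi-square per degree of freedom over genes with at least 20 counts in the pair, and pairs between groups by 110.7 to 123.7, so no library was taken for a duplicate of another.

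The gene lists, the tests, the rule for named genes and the rule for silent genes were fixed before the data were examined. The lists, 26 in number, were 20 of biology and 6 of checks, and the 25 with at least 5 tested members were tested with camera (preset correlation between genes of 0.01, limma 3.58.1), adjusted over the lists. Camera compares a list with all other tested genes. The self-contained test fry asks whether a list's genes move, on balance, 1 way, and compares nothing with other genes. It called 16 lists higher and 6 lower, against 12 and 4 for camera, and none of the 16 lists called by camera held with an estimated correlation, although 9 of the 25 lists had an unadjusted p under 0.05. That setting also rests camera's test on the few residual degrees of freedom of 6 libraries, so a lost call need not come from correlation between genes. The epithelial list had an estimated correlation of 0.0097, near the preset, yet its unadjusted camera p went from 0.0015 to 0.0332. For the mesenchymal list, with an estimated correlation of -0.0299, it went from 4.3e-09 to 0.0029. Other called lists had far higher estimated correlations, among them 0.9543 for mitochondrially encoded genes, 0.6706 for mitosis and 0.3173 for cholesterol synthesis. For those lists, correlation and the few degrees of freedom were not told apart as reasons for a lost call. In the 16 called lists of these 25, except the endothelial markers, the estimated correlation gave the highest adjusted p of all alternatives. Named genes were the 6 largest rises and the 6 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM and groups that do not overlap. To these were added DNMT1, DNMT3A and DNMT3B, and in each list of biology the 2 members with the smallest adjusted p, or 4 where the list had at least 10 members past the threshold. The rule gave 82 genes, of which 48 rose and 34 fell, and 3 of these are not reported here. Any other gene is said to have been chosen after its values were seen. The medians of 3 lists hold a member with 3 or fewer DMSO counts (CDH13, CSF3 and FLT1), and were the same with that member at its lower bound.

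The alternatives were median-of-ratios factors, library totals alone, upper-quartile factors, no filter on low counts, a filter of 10 counts in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) with a pseudocount of 1, unrounded counts, the replicate number as a block, each library left out in turn, an estimated correlation and fry. Mitochondrial genes left out before scaling, 11 further gene lists, and library totals for the on and off counts were added after the main results had been seen.

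The edgeR, DESeq2 and limma-voom steps were tested on simulated counts drawn from the means and library sizes of these libraries, with 200 planted changes. With 18609 genes tested, edgeR recovered 28 of 50 genes changed 1.25-fold, 33 of 50 changed 1.5-fold, 43 of 50 changed 2-fold and 50 of 50 changed 4-fold. It also called 17 of 18409 tested genes with no planted change. The planted genes were above a minimum mean count and changed in equal numbers up and down. In the data 70.53% of tested genes were called. The simulation therefore does not test scaling under so many changes, or recovery at low counts.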

Results

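RNA was sequenced from OVCAR5, an established human cell line used as a model of ovarian cancer, after 3 days with 100 nM NTX301 or with its solvent, dimethyl sulfoxide (DMSO). NTX301 is named in the labels as a DNA hypomethylating agent, that is, a drug that lowers the methylation of cytosines in DNA. Each treatment had 3 libraries, and the only comparison in the labels is NTX301 against DMSO. The DMSO libraries held 25572170, 25743732 and 22131175 estimated counts in total, and the NTX301 libraries 23194160, 23842859 and 23777071. The labels do not say whether the 3 libraries of a treatment came from separate cultures, so the p-values measure the spread between these libraries, which includes no difference between cultures if they did not. The floor for a gene without counts in a group was 3 counts over the 3 libraries, which is 0.0439 CPM (counts scaled to a common library size) with DMSO and 0.0394 CPM with NTX301, and floors and counting intervals cover counting error only.

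The comparison asks which genes and gene groups change when OVCAR5 cells are exposed to the drug. With NTX301, 46 of 49 tested genes of DNA replication, 42 of 42 of mitosis and 33 of 45 of DNA repair rose, while 19 of 29 genes of fatty acid synthesis and 23 of 25 of cholesterol synthesis fell. Camera, a test of gene lists, called these 5 lists, but none held with an estimated correlation (adjusted p = 0.0928, 0.1329, 0.0928, 0.0869 and 0.1186 with an estimated correlation, in this order). The estimated correlations were 0.1524, 0.6706, 0.0585, 0.0332 and 0.3173 in the same order, against a preset of 0.01. Estimating the correlation also leaves the test few degrees of freedom, so these values do not show whether correlation between genes undoes the calls. TOP2A, the topoisomerase that untangles chromosomes in dividing cells, went from 312 ± 18.4 CPM with DMSO to 934 ± 13.0 CPM with NTX301 (mean ± SD, n = 3 each). SCD, the desaturase that makes monounsaturated fatty acids, went from 2595 ± 19.05 to 276 ± 24.02 CPM (n = 3 each). SPARC, a secreted matrix glycoprotein, went from 16.2 ± 1.19 to 223 ± 5.77 CPM (n = 3 each).

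Of 19029 genes tested, 6744 rose and 6677 fell with NTX301 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among them 2541 rose and 1627 fell by 2-fold or more, 830 rose and 193 fell by 4-fold or more, and 325 rose and 17 fell by 8-fold or more by the fitted fold. The first principal component of log2 CPM held 79.85% of the variance and separated the treatments. On the second, with 6.34%, DMSO replicate 3 stood apart at -34.47, against 22.54 and 13.47 for DMSO replicates 1 and 2. The groups did not overlap in 73.68% of the tested genes, against 10% by chance for 3 against 3. Without a scaling factor, 8793 genes rose and 4732 fell (65.01% of calls rose, against 50.25% with TMM), and the median log2 fold change of all tested genes was 0.21. On log2(TPM + 1), 8652 rose and 4318 fell (66.71% rose). Fold changes below are therefore relative to the typical gene.

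**Figure D1:**
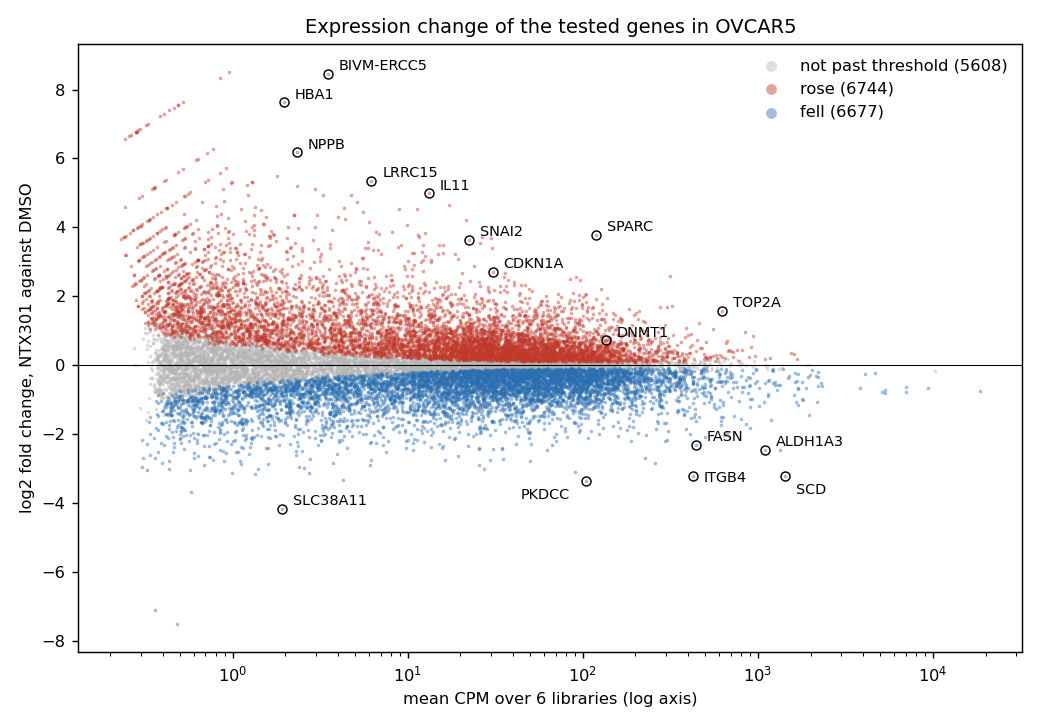
Fitted log2 fold change of each tested gene (vertical axis, NTX301 against DMSO) against its mean CPM over the 6 libraries (horizontal log axis), with red points for the 6744 genes that rose, blue points for the 6677 that fell and grey points for the rest. Circled genes are named in the text, and the fitted values of genes with few or no counts in a group, which form diagonal streaks at low CPM, depend on a prior count.

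The largest rises among genes averaging at least 1 CPM were in genes close to silent with DMSO. HBA1, an alpha globin gene (ENSG00000206172.8, chromosome 16, 176680 to 177522 in GRCh38), had 1 count over the DMSO libraries and 299 over the NTX301 libraries, a ratio of 268.7 with a 95% counting interval of 47.86 to 10650. HBA1 shares nearly all of its coding sequence with HBA2, so the split of reads between these copies is uncertain. BIVM-ERCC5, the readthrough transcript of BIVM and ERCC5 (ENSG00000270181.3, chromosome 13, 102799110 to 102875994), had 1 and 529 counts, a ratio of 475.4 with an interval of 84.95 to 18810. The 1 count of each lay in DMSO replicate 2. The NTX301 libraries ranged from 3.53 to 12.2 CPM for BIVM-ERCC5. It overlaps BIVM and ERCC5 on the same strand, so its level rests on how reads were divided among these genes. NPPB, which encodes the brain natriuretic peptide precursor (chromosome 1, 11857464 to 11858931), went from 0.0582 ± 0.0234 to 4.60 ± 0.730 CPM. BATF3, a transcription factor of the AP-1 family, rose by 5.48 ± 0.38 on the log2 scale (estimate ± SE). LRRC15, a membrane protein found on activated fibroblasts, rose by 5.34 ± 0.24 to 12.1 ± 0.681 CPM, and GLYATL3, a glycine N-acyltransferase-like gene, by 5.31 ± 0.35.

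The largest falls were in SLC38A11, PKDCC, TBC1D3D, SCD, ITGB4 and DRD2. PKDCC, a secreted tyrosine kinase (ENSG00000162878.13, chromosome 2, 42048020 to 42058528), went from 190.4 ± 12.9 to 18.5 ± 1.64 CPM, 10.3-fold lower. ITGB4, the integrin beta 4 subunit of hemidesmosomes (ENSG00000132470.14, chromosome 17, 75721328 to 75757818), went from 773 ± 26.6 to 82.4 ± 3.38 CPM, 9.39-fold lower with an edgeR adjusted p of 4.4e-12. SLC38A11, a member of an amino acid transporter family, went from 3.65 ± 0.778 to 0.197 ± 0.0675 CPM, and DRD2, the D2 dopamine receptor, from 2.42 ± 0.431 to 0.263 ± 0.113 CPM. TBC1D3D belongs to a cluster of near-identical genes and is uncertain. It fell in edgeR's test (log2 -3.33 ± 0.65, adjusted p = 0.00068) and was not past the threshold in DESeq2 (adjusted p = 0.0704, range over the alternatives 7.3e-07 to 0.0704). Its log2 fold change was -6.24 without NTX301 replicate 1 and -2.74 without NTX301 replicate 2.

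Among DNA methyltransferases, the maintenance enzyme DNMT1 (chromosome 19, 10133345 to 10231286) went from 102 ± 3.16 to 168 ± 5.77 CPM and the de novo enzyme DNMT3B from 5.50 ± 0.131 to 14.1 ± 0.893 CPM, both rises (log2 0.72 ± 0.04 and 1.36 ± 0.09). DNMT3A, the other de novo enzyme, fell from 56.6 ± 1.57 to 45.7 ± 1.21 CPM (log2 -0.31 ± 0.04, edgeR adjusted p = 5.9e-05), but was not past the threshold without a scaling factor (adjusted p = 0.0707) and had the opposite sign on log2(TPM + 1) (0.099, adjusted p = 0.2445, range over the alternatives 2.3e-06 to 0.2445). Of 23 tested genes of the DNA methylation machinery, 13 rose and 7 fell (13 and 8 adjusted over the list alone). APOBEC3B, a cytidine deaminase, rose by 1.72 ± 0.06 and GADD45A, a stress gene linked to demethylation, by 0.99 ± 0.05, while ZBTB4, which binds methylated DNA, fell by 1.01 ± 0.06. The list was higher by camera (median log2 fold change 0.31, adjusted p = 0.0422), a call absent with an estimated correlation (adjusted p = 0.46 with an estimated correlation). It was also absent with limma-voom (adjusted p = 0.0869), on log2(TPM + 1) (0.064), and without DMSO replicate 1 (0.0514) or 2 (0.066), and its camera adjusted p ranged from 0.0095 to 0.46 over the alternatives.

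Cancer-testis antigens, genes active in the testis and in some tumours and methylated elsewhere, gave few counts in either group, and of 52 only MAGEB2 was expressed enough to be tested. MAGEB2 (chromosome X, 30215560 to 30220089) had 0 counts over the DMSO libraries and 70 over the NTX301 libraries, at least 20.97-fold higher against a floor of 3 counts over the group. All 52 together had 33 counts with DMSO and 233 with NTX301 (ratio 6.345, 95% counting interval 4.394 to 9.435), and 163 of the latter lay outside MAGEB2. Of 8 tested germline genes, 5 rose and 1 fell (the same adjusted over the list alone), with TEX14, needed for germ cell bridges, going from 0.624 ± 0.198 to 6.61 ± 0.632 CPM and RPL39L, a testis-enriched ribosomal protein gene, rising by 1.33 ± 0.09 on the log2 scale. As a list they were not called by camera (median 1.23, adjusted p = 0.0959), and were higher by fry (adjusted p = 0.00014). Their median ranged from 0.38 to 1.43 over the alternatives. By the rule for silent genes, 16 genes were off with DMSO and on with NTX301 and 0 the other way round. COL8A1, a collagen gene chosen after its values were seen, had 0 and 128 counts, at least 38.3-fold higher against the floor over the group. The count of 16 was 34 without DMSO replicate 1, 29 without DMSO replicate 2 and 28 without DMSO replicate 3. The count of 0 was 1 without DMSO replicate 3 and without NTX301 replicate 1, 2 or 3. With a library left out the rule covers fewer libraries, so these counts can only stay or grow.

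Of 31 tested genes listed as tumour suppressors methylated in ovarian cancer, 20 rose and 6 fell (the same adjusted over the list alone). SPARC and COL1A1 rose by 3.78 ± 0.05 and 1.82 ± 0.05 on the log2 scale and BRCA1, a homologous recombination gene, by 1.44 ± 0.04. SPARC and COL1A1 also stand in the mesenchymal list and BRCA1 in the DNA repair list, so these rises are not separate from those below. None of them was silent with DMSO (16.2, 13.7 and 31.6 CPM in this order). DAPK1, a death-associated kinase, moved the other way, from 194 ± 3.54 to 68.5 ± 1.69 CPM. The list was higher by camera (median 0.57, adjusted p = 0.0012, and adjusted p = 0.0928 with an estimated correlation).

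All 42 tested genes of mitosis and the G2/M transition rose, 39 of them by 2-fold or more (42 adjusted over the list alone, median log2 fold change 1.45). KIF23 and ECT2, which act in cytokinesis, rose by 1.76 ± 0.04 and 1.69 ± 0.04, TOP2A by 1.58 ± 0.05, and TPX2, a spindle assembly factor, by 1.58 ± 0.05. Of 49 tested genes of DNA replication and S phase, 46 rose and 1 fell (the same adjusted over the list alone, median 0.86). ORC6, a subunit of the origin recognition complex, rose by 1.71 ± 0.05, the clamp loader subunit RFC3 by 1.71 ± 0.05, the replication licensing factor CDC6 by 1.53 ± 0.05, and RRM2, a subunit of ribonucleotide reductase, by 1.29 ± 0.05. Of 45 DNA repair genes, 33 rose and 3 fell (33 and 4 adjusted over the list alone, median 0.58). The Fanconi anaemia gene FANCI rose by 1.67 ± 0.04, the checkpoint kinase CHEK1 by 1.47 ± 0.04, and BRCA1 by 1.44 ± 0.04. Camera called these lists higher with adjusted p = 3.6e-38, 1.5e-18 and 4.1e-09 in this order. None held with an estimated correlation (adjusted p = 0.1329, 0.0928 and 0.0928 with an estimated correlation, in the same order).

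**Figure D2:**
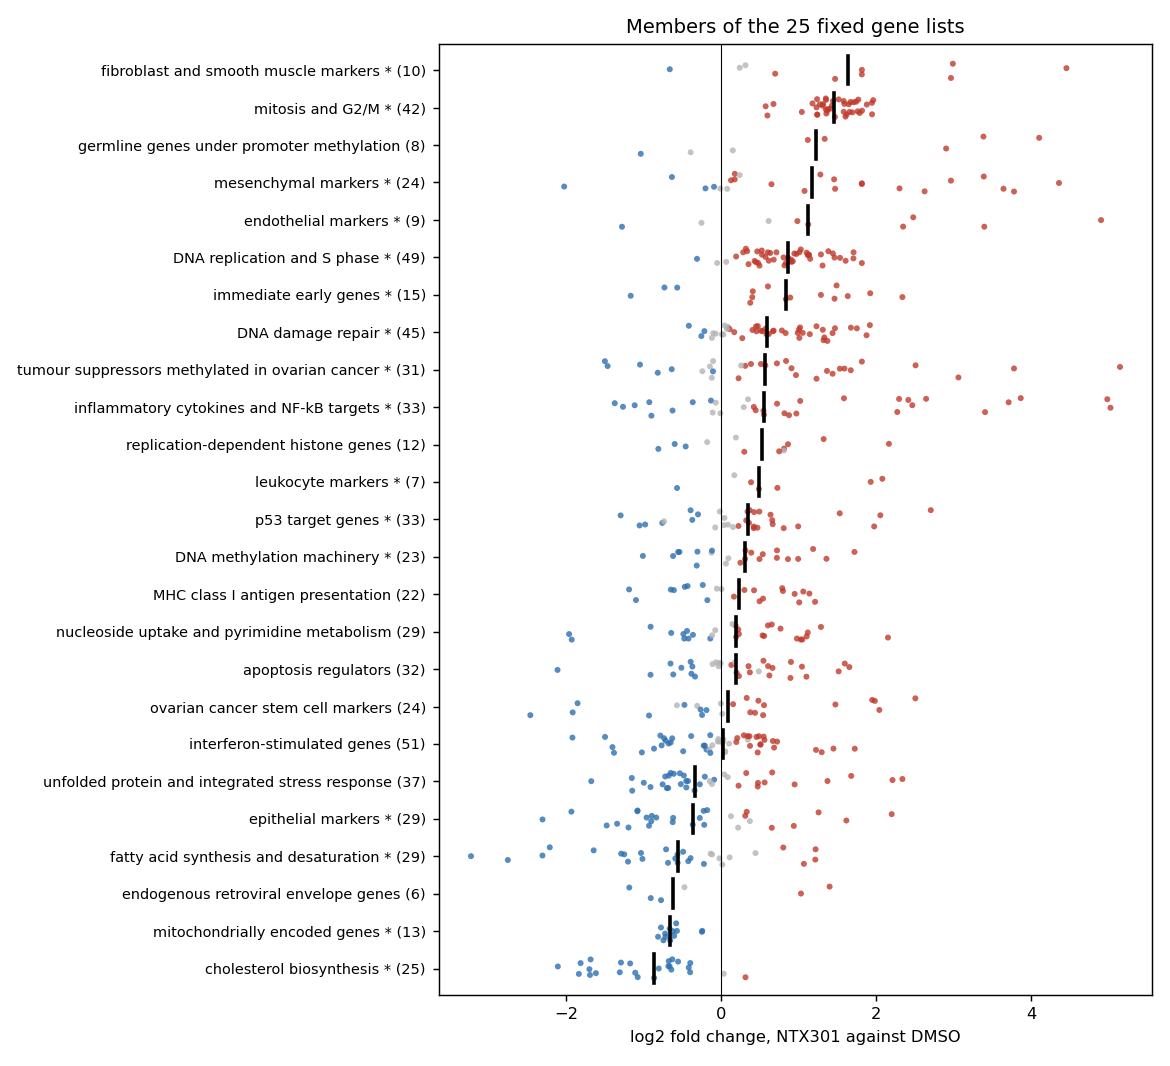
Log2 fold change (horizontal axis, NTX301 against DMSO) of each tested member of the 25 gene lists with at least 5 tested members, 1 point per gene, red for genes that rose, blue for genes that fell and grey for genes not past the threshold. Black bars are list medians, numbers in brackets are tested members, and an asterisk marks the 16 lists called by camera, among which mitosis and G2/M has all 42 points above 0 and cholesterol biosynthesis 23 of 25 genes that fell.

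Among p53 targets, CDKN1A, which encodes the p21 inhibitor of cyclin-dependent kinases, went from 8.11 ± 0.571 to 52.98 ± 2.52 CPM (log2 2.70 ± 0.07). AEN, an apoptosis-enhancing nuclease, rose by 2.05 ± 0.06 and PMAIP1, the pro-apoptotic protein NOXA, by 1.53 ± 0.05, while CCNG1, cyclin G1, fell by 0.76 ± 0.04. Of 33 tested members 19 rose and 7 fell (the same adjusted over the list alone), with a median of 0.34 and a camera adjusted p of 0.0158. The call was lost in limma-voom (adjusted p = 0.0517) and on log2(TPM + 1) (0.064), and did not hold with an estimated correlation (adjusted p = 0.2766 with an estimated correlation, camera range over the alternatives 0.0024 to 0.2766). Of 32 apoptosis regulators 16 rose and 9 fell (the same adjusted over the list alone, median 0.19, camera adjusted p = 0.5937, fry adjusted p = 0.0149). Cytochrome c (CYCS) rose by 0.89 ± 0.06 and survivin (BIRC5), which is also a mitotic gene, by 1.52 ± 0.09. TNFSF10, the death ligand TRAIL, went from 174 ± 11.95 to 40.2 ± 2.73 CPM.

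FASN, the fatty acid synthase, went from 739 ± 8.21 to 149 ± 12.3 CPM, 4.95-fold lower. SREBF1 and SREBF2, which encode the transcription factors that drive fatty acid and cholesterol synthesis, changed by -2.21 ± 0.04 and -1.69 ± 0.04 on the log2 scale, and ELOVL6, a fatty acid elongase, fell by 1.65 ± 0.05. Of 29 tested genes of fatty acid synthesis and desaturation, 19 fell and 4 rose (the same adjusted over the list alone, median -0.56). Their median was -0.36 without a scaling factor. Of 25 cholesterol synthesis and uptake genes, 23 fell and 1 rose (the same adjusted over the list alone, median -0.87). DHCR7, the last enzyme of one branch of cholesterol synthesis, went from 254 ± 4.997 to 71.97 ± 2.12 CPM, and INSIG1, a sterol-sensing regulator, fell by 1.84 ± 0.05 on the log2 scale. Camera called both lists lower (adjusted p = 2.3e-09 for fatty acids and 2.9e-17 for cholesterol). Neither held with an estimated correlation (adjusted p = 0.0869 and 0.1186 with an estimated correlation).

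Mesenchymal markers rose in 17 of 24 tested genes and fell in 4 (the same adjusted over the list alone, median 1.18). SNAI2, a transcriptional repressor of epithelial genes, went from 3.31 ± 0.164 to 41.5 ± 1.90 CPM, and TAGLN, an actin-binding protein of smooth muscle, from 5.29 ± 0.308 to 55.4 ± 3.21 CPM. COL1A1, a chain of type I collagen, went from 13.7 ± 0.172 to 48.3 ± 0.7995 CPM. FN1, which encodes fibronectin and was chosen after its values were seen, fell from 1028 ± 43.4 to 252 ± 56.6 CPM. Of 29 tested epithelial markers, 19 fell and 7 rose (the same adjusted over the list alone, median -0.37). Without a scaling factor the epithelial median was -0.16. KRT8, a keratin of simple epithelia, went from 2248 ± 78.4 to 1062 ± 36.1 CPM, the epithelial transcription factor ELF3 fell by 1.35 ± 0.05 and the tight junction protein TJP3 fell by 1.93 ± 0.07, while the keratin KRT7 rose by 1.26 ± 0.05. KRT8, KRT7 and ELF3 overlap KRT18, KRT7-AS and ELF3-AS1 on the other strand, in this order, and their reads may not have been separated. Camera called the mesenchymal list higher (adjusted p = 1.8e-08) and the epithelial list lower (adjusted p = 0.0037). Neither held with an estimated correlation (adjusted p = 0.0716 and 0.1186 with an estimated correlation). Fibroblast and smooth muscle markers, 7 of whose 16 members stand in another list, moved with the mesenchymal list (7 of 10 tested genes rose, median 1.64).

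Ovarian cancer stem cell markers moved both ways, 12 of 24 rising and 8 falling (the same adjusted over the list alone). ALDH1A3 and ALDH1A1, aldehyde dehydrogenases whose activity is used to sort such cells, went from 1854 ± 26.3 to 336 ± 32.7 CPM and from 175 ± 9.18 to 46.4 ± 1.58 CPM. The surface glycoprotein CD24 fell by 1.85 ± 0.05 on the log2 scale, and JAG1, a Notch ligand, rose by 1.95 ± 0.07. ALDH1A3 overlaps the antisense gene ALDH1A3-AS1, and as no strand setting is stated their reads may not have been separated. The list was not called (median 0.08, mean 0.15, camera direction down with adjusted p = 0.9674), so its median and its test differ in sign.

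**Figure D3:**
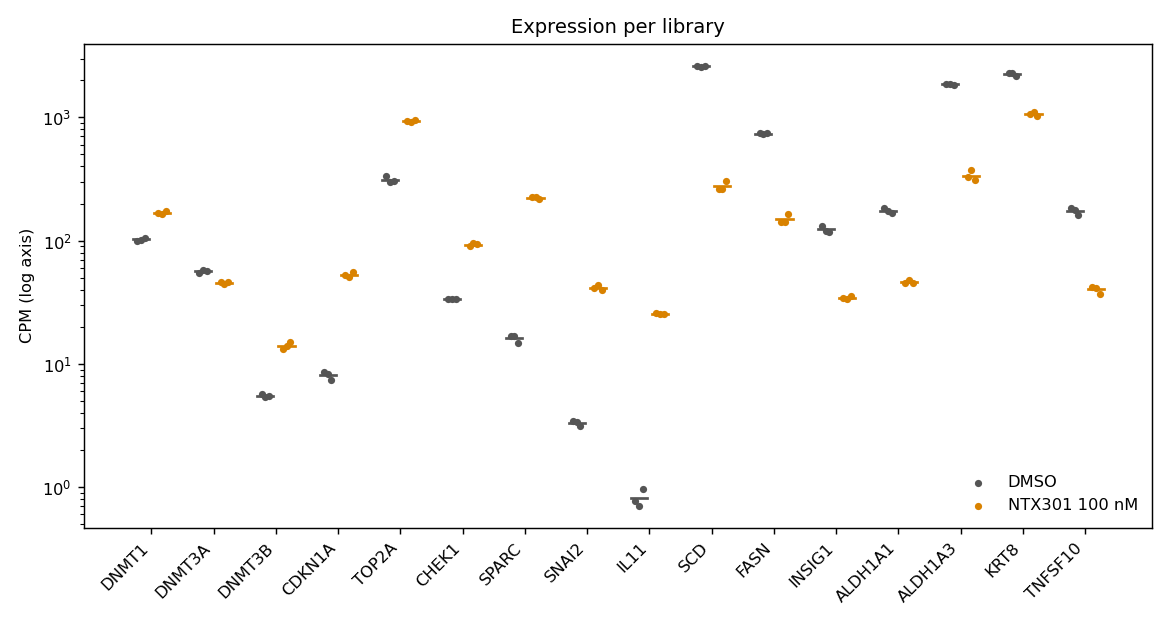
CPM of 16 named genes (vertical log axis) in each of the 3 DMSO libraries (grey points) and the 3 NTX301 libraries (orange points), with a bar at each mean. For each gene shown the points of the treatments do not overlap, as for SPARC (means 16.2 and 223 CPM) and SCD (means 2595 and 276 CPM).

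Inflammatory cytokines and NF-kB targets rose in 20 of 33 tested genes and fell in 8 (the same adjusted over the list alone). IL11, a cytokine of the IL-6 family, went from 0.811 ± 0.134 to 25.6 ± 0.337 CPM (log2 4.98 ± 0.11), and PTGS2, the inducible cyclooxygenase, from 1.66 ± 0.107 to 21.7 ± 2.28 CPM. The acute-phase gene SAA1, whose reads may be shared with SAA2, rose by 2.30 ± 0.09, and NFKBIZ, a nuclear regulator of NF-kB, fell by 1.38 ± 0.05. The list was higher by camera (median 0.55, adjusted p = 0.0064), but not on log2(TPM + 1) (adjusted p = 0.064), nor with an estimated correlation (adjusted p = 0.46 with an estimated correlation, camera range over the alternatives 0.00019 to 0.46). Leukocyte markers (5 of 7 rose, camera adjusted p = 0.021, and adjusted p = 0.2766 with an estimated correlation) and immediate early genes (12 of 15 rose, camera adjusted p = 0.0101, and adjusted p = 0.3635 with an estimated correlation) moved in the same direction. Interferon-stimulated genes were split, with 20 of 51 rising and 20 falling (the same adjusted over the list alone, median 0.02, mean -0.03 and camera direction down, adjusted p = 0.4474, with fry's adjusted p 0.0015 in the same direction). The antiviral OAS1 fell by 1.40 ± 0.08, LGALS3BP, a secreted glycoprotein, fell by 1.38 ± 0.05, and the membrane proteins IFITM1 and IFITM2, which are similar in sequence, changed by -0.79 ± 0.04 and -0.87 ± 0.05. Of 22 genes of MHC class I antigen presentation, 12 rose and 8 fell (the same adjusted over the list alone, median 0.23, camera adjusted p = 0.3117, fry adjusted p = 0.0196). HLA-B, a class I heavy chain, went from 279 ± 13.1 to 646 ± 16.6 CPM and the peptide transporter genes TAP1 and TAP2 rose by 1.01 ± 0.06 and 0.95 ± 0.04, while TAPBP, the loading factor tapasin, fell by 1.19 ± 0.04. HLA-B overlaps HLA-C on the same strand, so its level rests on how reads were divided between these genes.

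Among stress response genes, PPP1R15A, which encodes the stress-induced phosphatase subunit GADD34, rose by 2.21 ± 0.04 on the log2 scale, the transcription factor DDIT3, also called CHOP, by 1.68 ± 0.05 and the secreted hormone STC2 by 1.37 ± 0.04, while DDIT4, an inhibitor of mTORC1 signalling, fell by 1.68 ± 0.05. Of the 37 tested genes of the unfolded protein and integrated stress responses, 11 rose and 22 fell (the same adjusted over the list alone). The list was not called (median -0.34, camera adjusted p = 0.193), and was lower without a filter on low counts (adjusted p = 0.0248, camera range over the alternatives 0.0248 to 0.7133) and by fry (0.0075). It was not called with an estimated correlation (adjusted p = 0.7133 with an estimated correlation). Among 29 genes of nucleoside uptake and pyrimidine metabolism, 16 rose and 10 fell (17 and 10 adjusted over the list alone). UPP1, uridine phosphorylase, went from 18.8 ± 0.470 to 83.5 ± 4.78 CPM, while the nucleotidase NT5C fell by 1.93 ± 0.06 and SLC29A2, an equilibrative nucleoside transporter, fell by 1.96 ± 0.06. That list was not called (median 0.19, camera adjusted p = 0.0959), and was higher without a scaling factor (adjusted p = 0.0148), in DESeq2 (0.0373), with the replicate number as a block (0.0426) and by fry (0.00097), with a camera range over the alternatives of 0.0148 to 0.5115, the highest being adjusted p = 0.5115 with an estimated correlation. Of 6 tested endogenous retroviral envelope genes, 2 rose and 3 fell (2 and 4 adjusted over the list alone, median -0.63, camera adjusted p = 0.9072). ERVK3-1 rose by 1.03 ± 0.07 and ERV3-1 fell by 0.78 ± 0.06, and other retroviral copies were not measured as genes here.

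Lists fixed as checks on other cell types and on RNA quality also moved. Fibroblast and smooth muscle markers rose in 7 of 10 tested genes and fell in 1 (median 1.64, camera adjusted p = 0.0023, and adjusted p = 0.1665 with an estimated correlation). Endothelial markers rose in 6 of 9 and fell in 1 (median 1.12, camera adjusted p = 0.014, and adjusted p = 0.1369 with an estimated correlation). Leukocyte markers rose in 5 of 7 and fell in 1 (median 0.49, camera adjusted p = 0.021, and adjusted p = 0.2766 with an estimated correlation), a call lost without DMSO replicate 1 (adjusted p = 0.0515). The endothelial and leukocyte calls were also lost in limma-voom (adjusted p = 0.0744 and 0.0523). Immediate early genes, which respond within minutes to handling or growth factors, rose in 12 of 15 and fell in 3 (median 0.83, camera adjusted p = 0.0101, and adjusted p = 0.3635 with an estimated correlation). The fibroblast, endothelial, leukocyte and immediate early lists were not called on log2(TPM + 1) (adjusted p = 0.06, 0.2326, 0.1222 and 0.0608). Their medians there were 0.88, 0.34, 0.67 and 0.86 in the same order. Over the alternatives their camera adjusted p ranged from 0.00023 to 0.1665, from 0.0027 to 0.2326, from 0.0155 to 0.2766 and from 0.00027 to 0.3635 in this order. Replication-dependent histone genes rose in 6 of 12 and fell in 3 (median 0.52, camera adjusted p = 0.8449). All 13 mitochondrially encoded genes fell (median -0.66, and -0.45 without a scaling factor, camera adjusted p = 0.0023, and adjusted p = 0.5115 with an estimated correlation), and their share of counts was 8.99 ± 0.720% with DMSO and 6.94 ± 0.462% with NTX301 (n = 3 each). In these 6 check lists the counts adjusted over the list alone were the same. Genes with at least 1 count numbered 28058 to 28646 in the DMSO libraries and 30397 to 30586 in the NTX301 libraries.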

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

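Leaving out mitochondrial genes, the further gene lists, and library totals for on and off counts were chosen after seeing the data. Of the 82 named genes, 80 kept their sign and their side of the threshold in all 17 refits. The exceptions were DNMT3A, which reversed on log2(TPM + 1) to 0.099314, and TBC1D3D in DESeq2. Most named genes were picked for a small adjusted p or a large change in these same libraries, so such stability was likely beforehand. The 6744 rises and 6677 falls became 6123 and 5978 in DESeq2, and 12081 of its 12101 calls were shared, 0 with the opposite sign. On log2(TPM + 1) falls numbered 4318, and 2-fold falls 547. There 82.48% of the calls of the main fit were shared, and 79 calls had the opposite sign. With library totals alone, 2-fold falls numbered 1054, as the scale shifts by a median of 0.206. Lists called higher numbered 5 on log2(TPM + 1). With an estimated correlation 0 lists were called higher and 0 lower. Genes switched on were 61 from 0.5 CPM, 2 from 2 CPM, 2 when off means 0 counts, and 17 to 34 with a library left out. Genes switched off were 2 from 0.5 CPM and 0 to 1 with a library left out. These thresholds shift the counts by construction, and the cause of the other changes was not tested. Counts near the floor limit the on and off numbers.

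The labels number the replicates 1 to 3 in both groups. With the replicate block, 6837 genes rose and 6749 fell, and 13244 calls were shared. Nucleoside genes were then called higher (adjusted p = 0.0426), against 0.0959 without the block and adjusted p = 0.5115 with an estimated correlation. Deviations of same-numbered libraries correlated at 0.0805, -0.0277 and 0.0431, none above 0.1, and not every sample correlated best with its own number, so the numbers were not read as pairs.

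Lists that neither camera nor fry called changed the direction of the test under the settings named here, where they had these medians. Ranges in brackets cover all 6 fits that leave a library out. Stem cell markers had 0.2897 with library totals, 0.0843 in limma-voom, 0.2486 on log2(TPM + 1), and 0.0771 without NTX301 replicate 1 (0.0516 to 0.151). Retroviral envelope genes had 1.0853 without a filter, -0.4758 with at least 10 counts, -0.4669 without mitochondrial genes, -0.3524 without DMSO replicate 2, -0.5092 without DMSO replicate 3 and -0.3847 without NTX301 replicate 1 (-0.6424 to -0.3524). Of the added lists, hypoxia targets had 0.1337 without a filter, 0.1549 without DMSO replicate 2 (0.1131 to 0.2049), and 0.1618 where fry's direction was opposite to camera's. Glycolysis had 0.2208 on log2(TPM + 1). The respiratory chain had -0.0434 without a filter, -0.0844 without DMSO replicate 3 and -0.0263 without NTX301 replicate 1 (-0.0844 to 0.0655). Keratins had 1.2282 without a filter, 0.5657 in limma-voom, 0.7628 on log2(TPM + 1), 0.5831 without DMSO replicate 1, 0.5536 without DMSO replicate 2 and 0.5575 without NTX301 replicate 1 (0.527 to 0.5831). The cause was not tested.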

Other observations

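Chosen only after results had been seen were the further gene lists in this part, the genes named from them, and the tests of scaling as a cause (1 of whose 5 scalings was not planned), of YAP and TAZ targets, of abundant genes of other cell types, of thinned libraries and of other splits. Ribosome biogenesis genes, which build ribosomes in the nucleolus, rose in 26 of 30 tested genes and fell in 1 (median 0.65 on the log2 scale, camera adjusted p = 6.2e-10, and adjusted p = 0.0675 with an estimated correlation). LYAR, a nucleolar protein, rose by 1.87 ± 0.12 on the log2 scale. Serum response factor and actin cytoskeleton genes rose in 14 of 22 and fell in 5 (median 0.66, camera adjusted p = 0.00017, and adjusted p = 0.1193 with an estimated correlation), with the smooth muscle gene CNN1 going from 0.479 ± 0.0855 to 10.7 ± 0.217 CPM while ACTB, the main cytoplasmic actin, fell by 0.60. TGF-beta targets rose in 13 of 20 and fell in 6 (median 0.56, camera adjusted p = 0.0097, and adjusted p = 0.1227 with an estimated correlation), a call also lost in limma-voom (adjusted p = 0.1029) and on log2(TPM + 1) (0.2487, camera range over the alternatives 0.00044 to 0.2487). Lysosome genes fell in 21 of 30 and rose in 6 (median -0.47, camera adjusted p = 0.0001, and adjusted p = 0.5157 with an estimated correlation), among them CTSD, the protease cathepsin D, from 2891 to 1052 CPM.

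Other lists moved both ways and were not called by camera. Hypoxia-inducible factor targets rose in 12 of 25 genes and fell in 8 (median 0.16, camera adjusted p = 0.9888), glycolysis genes rose in 7 of 19 and fell in 8 (median 0.01, adjusted p = 0.6095), and the nuclear-encoded respiratory chain rose in 13 of 35 and fell in 10 (median -0.02, and 0.19 without a scaling factor, adjusted p = 0.9888), although all 13 mitochondrially encoded genes fell. Imprinted genes rose in 8 of 18 and fell in 5 (median 0.18, adjusted p = 0.0605), and were called higher by fry (2.1e-05), without a scaling factor (0.0202), without a filter (0.0235), in DESeq2 (0.0413) and without NTX301 replicate 2 (0.026). Over the alternatives their camera adjusted p ranged from 0.0202 to 0.6564, with adjusted p = 0.2079 with an estimated correlation. Among them H19 and IGF2, neighbours under shared control, rose by 1.76 and 1.60 while KCNQ1OT1, an antisense RNA, fell by 1.73. Keratins rose in 10 of 15 and fell in 5 (median 0.57, adjusted p = 0.9888), with KRT81 rising from 0.289 to 9.14 CPM while KRT8 and KRT18 fell. The median, mean and camera direction differed in sign for glycolysis (mean -0.07, down), the respiratory chain (mean 0.05, up) and keratins (mean 1.16, down), and fry's direction was down for hypoxia targets. Numbered ZNF genes rose in 120 of 366 and fell in 110 (median 0.04, adjusted p = 0.7906).

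Genes of the cell cycle rose although CDKN1A, an inhibitor of it, rose too, while sterol genes fell. Over 5 other scalings the median of the mitosis list stayed at 1.4585 or above and that of the cholesterol list at -0.6597 or below. These scalings put the median tested gene at 0.206 at most, so they could hardly have brought either list to 0. The signs of both lists thus did not depend on the choice among these scalings. All are relative to other genes, so a change in total RNA per cell was not tested. Sparser cultures with NTX301 may contribute, since growth and contact alter all of these groups, but the YAP and TAZ targets that would rise in sparse cells moved both ways, 11 of 21 rising and 7 falling (median 0.1257, camera adjusted p = 0.4152, fry adjusted p = 0.0031). Cell density therefore stays open, as does a shift in cell cycle phase as a response to the drug, which was not tested.

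Of tested markers of other cell types, 7 of 10 fibroblast, 6 of 9 endothelial and 5 of 7 leukocyte genes rose and 1 of each fell, with no list called with an estimated correlation (adjusted p = 0.1665, 0.1369 and 0.2766 with an estimated correlation). RNA from such cells would bring their abundant genes, and these stayed low: COL1A2, COL3A1, DCN and LUM together moved by -0.1997% of the rise of COL1A1, PECAM1, VWF, CDH5 and EMCN by 1.912% of the rise of ESAM, and PTPRC, LYZ, TYROBP and CD3E by -0.9364% of the rise of LAPTM5. COL1A2 had 0.039 CPM and PTPRC 0.091 CPM with NTX301. Summed, the abundant endothelial genes still rose slightly, from 5.11 ± 0.304 CPM with DMSO to 6.10 ± 0.257 CPM with NTX301. The fibroblast and leukocyte sums did not rise. Of the markers, 4 of 16 fibroblast, 5 of 15 endothelial and 6 of 23 leukocyte genes already had at least 1 CPM with DMSO, and 7, 0 and 0 in this order stand in another list. A candidate explanation is that OVCAR5 cells themselves express these genes after treatment, as a hypothesis found and tested on the same data.

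More genes were detected with NTX301, and among genes averaging under 1 CPM 29.43% rose and 10.14% fell by 2-fold or more, against 2.95% and 8.36% above 100 CPM. The tables argue against total depth as the cause. With each library thinned to the smallest total, the lowest NTX301 library still had 2133 more genes with a count than the highest DMSO library. DMSO replicates 1 and 2 had larger totals and fewer genes before thinning, so another result was unlikely. At equal totals the typical gene had more counts with NTX301 (median log2 fold change 0.206 without a scaling factor), and its part in the 2133 was not separated. Genomic DNA in the NTX301 libraries would raise genes that these cells do not use, but olfactory receptor genes had a ratio of 1.123 (95% counting interval 0.9754 to 1.293), below the 1.6 of other protein-coding genes under 1 CPM, and 75 of them had a count with DMSO and 72 with NTX301. This argues against genomic DNA as the whole cause. A smaller contribution is not excluded, since the interval reaches 1.293 and covers counting error only. Loss of promoter methylation at silent genes remains a possible explanation, and was not tested because no methylation values were analysed here.

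The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 with the highest count in each case: 6744 rises against at most 1 in another split, 6677 falls against 0, 2541 and 1627 changes of 2-fold or more against 1 and 0, and 16 gene lists against 12. Every other split mixes both treatments within its groups, so the treatment difference widens their spread and few gene calls follow by construction. The gene counts of these splits therefore do not measure chance. Camera, with the preset correlation, still called 5 to 12 lists in them. The groups of these splits hold unequal numbers of treated libraries, so the list counts do not measure chance either. They do show that such camera calls, and their small adjusted p, can arise where hardly any gene is called.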
